A study of Mus musculus with 6 samples.

How the data were processed

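Gene expression was measured by RNA sequencing in 6 libraries from the cerebral cortex of mice aged 2 months and labelled as C57BL/6. Per the labels, 3 libraries (replicates 1, 3 and 4) came from wild type animals and 3 (replicates 5, 6 and 7) from animals with both copies of Gtf2ird1 mutated. The series title describes the material as Gad2+ neurons, and how these cells were isolated is not given in the sources used here. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made with a kit for stranded total RNA. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these libraries, and part of that spread is technical to an unknown degree.

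The deposited values are raw counts of reads per gene, 1 file per library, and were not normalized or pooled. Per the submitters' processing notes, the processing named Trim Galore 0.60, STAR 2.7, HTSeq 1.31 and the genome build mm10. The annotation release, the strand setting of the counting and the handling of reads that map to several places are not given in the sources used here. Each file ends with 5 summary lines that name no gene, and these stayed out of library totals and tests. Reads outside annotated genes made up between 40.0% and 58.2% of all reads in the deposited counts, and ambiguous reads between 1.94% and 14.5%. The line for reads with several alignments was 0 in all 6 files. Genes encoded by the mitochondrial genome had a count of 0 in every library, so mitochondrial content could not be used as a measure of RNA quality.

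The files hold 53379 gene identifiers, of which 53274 matched GENCODE M21, an annotation of GRCm38 (the assembly also named mm10), by Ensembl identifier without its version. The other 105 kept their identifier as name. Coordinates are 1-based positions from that annotation. Total gene counts per library lay between 13627501 and 30544144, so 3 counts, the limit that a count of 0 allows, corresponded to between 0.0982 and 0.22 CPM (counts scaled to library size). Shares of reads on 1 gene copy have exact Clopper-Pearson 95% intervals, which cover counting error only. Libraries of 1 group were compared pairwise by chi-square over genes. The lowest value per degree of freedom within a group was 57.1, so no pair agreed within sampling noise. Separate preparations of the same RNA can also differ beyond sampling noise, so this does not show that libraries came from separate animals. Every library was counted as 1 sample.

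Differential expression was tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default expression filter by group, robust shrinkage and Benjamini-Hochberg adjustment over the 17221 genes that passed the filter. An adjusted p of 0.05 was the threshold and tests were two-sided. Levels of named genes are CPM after TMM normalization, and levels of marker lists are CPM over all gene counts. Fold changes are given as log2 fold change of the libraries labelled knockout over wild type, with the standard error derived from the F statistic. Single values were compared by exact permutation over the 6 libraries, for which 0.1 is the smallest two-sided p that 3 against 3 can give.

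There were 32 gene lists fixed before the data were examined, covering the Williams region, cell types, receptors, channels and cell states. Of these, 27 had at least 5 tested members and were tested as sets with camera from limma 3.58.1 at its preset correlation of 0.01, beside camera with an estimated correlation and fry. The lists for ependymal and choroid plexus cells, serotonin receptors and mitochondrially encoded genes had too few tested members, and the lists of library quality RNAs and sex-linked genes only describe the libraries. Called genes near Gtf2ird1 were counted within 10 Mb on each side and compared with all other tested genes by Fisher's exact test.

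Genes named in the text followed a rule fixed beforehand. It took Gtf2ird1, Gad1 and Gad2, then up to 10 genes with the largest change per direction that passed the threshold with a mean of at least 1 CPM and fully separated groups, then the 5 smallest adjusted p-values. Where fewer than 10 passed in a direction, the 5 genes with the smallest p that did not pass were added. Each list added up to 4 members with its smallest p-values. Other genes named, such as marker genes with high levels, parent genes of copies, sex-linked genes and genes called under 1 alternative, were chosen after their values were seen. Results for some genes that the rule would name are not reported here.

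Alternatives covered DESeq2 size factors, upper-quartile and total-count scaling, DESeq2 1.42.0 as the test, limma-voom, no robust shrinkage, other expression filters, leaving out each library, protein-coding genes alone, 1 surrogate variable from sva 3.50.0, an offset for GC content and length, and removal of mitochondrial, haemoglobin, rRNA and small RNA genes. A covariate for Y-linked reads, a looser threshold near Gtf2ird1 and an estimated correlation without 1 library in turn were added after the data were seen. The procedure was tested on simulated data for the comparison of knockout with wild type, with 17010 genes in the fit. It recovered 0% of genes changed 1.5-fold, 24% of genes changed 2-fold, 75.5% of genes changed 4-fold and 96% of genes changed 16-fold, and called 13 unchanged genes. The recovered genes numbered 0, 12, 37 and 48 at these folds, so the 13 false calls were not a negligible part of all calls. Simulated counts varied independently between genes, and the changed genes had a mean of at least 1 CPM. The cytosolic ribosomal protein list was also raised 1.5-fold as a set. The simulation lacked variation that many genes share between libraries, so these rates may not hold for the real data. Sequences of gene copies were aligned to the transcripts of their parents in the same annotation.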

Results

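The comparison asked how gene expression differed between cortical libraries from wild type mice and from mice labelled as lacking Gtf2ird1, a transcription factor gene of the chromosome region deleted in Williams syndrome. There were 3 libraries per group. The total gene count was 28933624, 13627501 and 16564664 in wild type replicates 1, 3 and 4, and 23020623, 16685959 and 30544144 in knockout replicates 5, 6 and 7. Ribosomal RNA took 17.5% of the gene counts in wild type replicate 3 and 6.2% in knockout replicate 6, and at most 1.51% in the other 4 libraries. The first principal component of log2 CPM held 50.1% of the variance and placed wild type replicate 1, at -20.56, on the side of the libraries labelled knockout, which lay between -56.32 and -26.18. Wild type replicates 3 and 4 lay at 72.46 and 63.08.

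Transcripts of microglia, the resident macrophages of the brain, were the most abundant marker transcripts in all 6 libraries. Csf1r, the receptor for colony stimulating factor 1, had a mean of 8520 CPM over the libraries, Cx3cr1 4250 CPM and P2ry12 3880 CPM. Of the 19 microglia and macrophage markers, 12 had a mean rank within the top 200 protein-coding genes. The median of this list was 1300 ± 188 CPM in wild type and 1270 ± 197 CPM in the libraries labelled knockout (SD, n = 3 each). The median of the 24 pan-GABAergic markers was 26.9 ± 20.4 CPM and 41.2 ± 11.8 CPM (SD, n = 3 each), so that the microglial median exceeded it between 19.9 and 109 times per library. The GABAergic list includes Maf, which had 597.3 CPM in wild type and is also a macrophage gene. Subtype markers were low: the median of the parvalbumin list was 0.81 CPM in wild type and 1.64 CPM in the libraries labelled knockout, and that of the somatostatin list 0.29 CPM and 0.513 CPM.

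**Figure D1:**
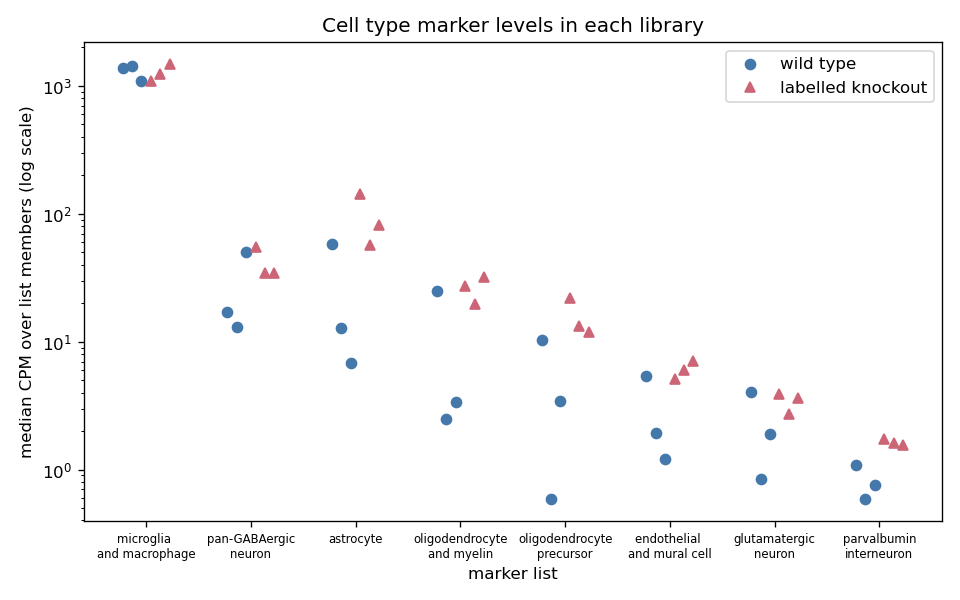
Median CPM over the members of 8 marker lists (log scale) in each of the 3 wild type libraries (circles) and the 3 libraries labelled knockout (triangles), 1 point per library. The microglia and macrophage list lies between 1090 and 1480 CPM and the pan-GABAergic list between 13.1 and 54.8 CPM, and 2 wild type libraries have the lowest astrocyte levels, at 12.7 and 6.82 CPM.

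Gtf2ird1 itself was not lower in the libraries labelled knockout. The gene (ENSMUSG00000023079.14) lies on the minus strand of chromosome 5 from 134357656 to 134456716 in GRCm38. Its level was 23.35, 31.54 and 52.68 CPM in wild type replicates 1, 3 and 4 and 49.69, 40.62 and 48.76 CPM in knockout replicates 5, 6 and 7. The means were 35.85 ± 15.13 and 46.36 ± 4.989 CPM (SD, n = 3 each), an exact permutation test gave a two-sided p of 0.4, and the log2 fold change was 0.37 ± 0.29 (SE; edgeR adjusted p = 0.703). The 95% interval of the fold ran from 0.813 to 2.06. A count over the whole gene sums all of its exons, and the mutated part is not given in the sources used here, so this value does not check the labels. Gad1 and Gad2, which encode the enzymes that make GABA, had log2 fold changes of 0.29 ± 0.55 (SE; edgeR adjusted p = 0.877) and 0.67 ± 0.54 (SE; edgeR adjusted p = 0.712). Gad1 ranged from 41.96 to 168.7 CPM within wild type alone. Its log2 fold change was near 0 or negative without wild type replicate 1, without wild type replicate 3 or without knockout replicate 5, at -0.04, -0.00369 and -0.02.

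**Figure D2:**
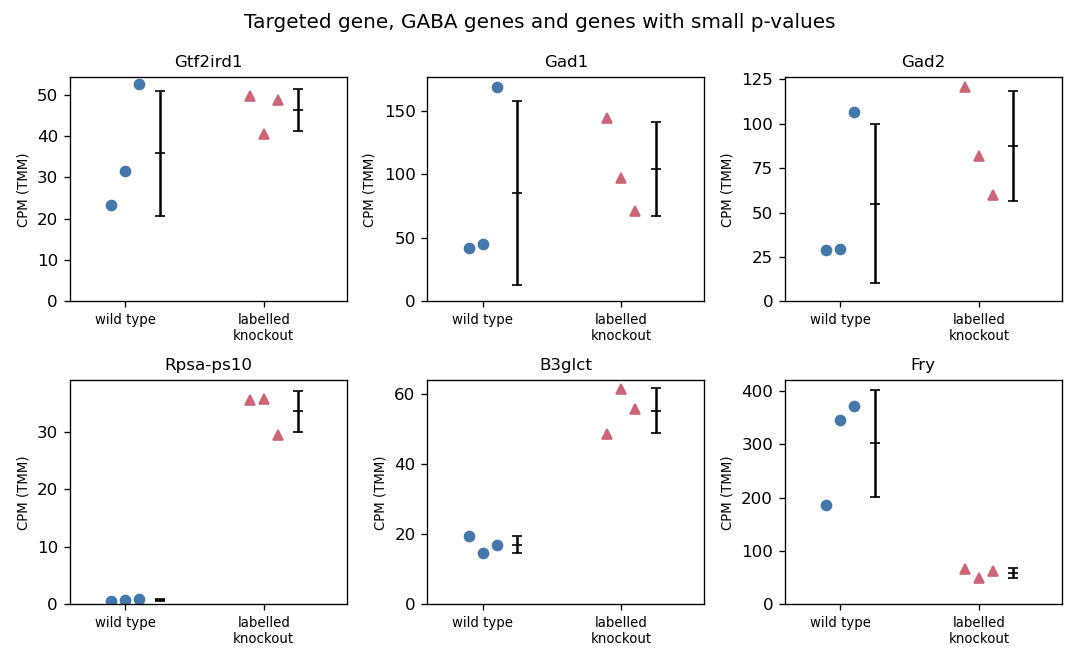
CPM after TMM normalization of Gtf2ird1, Gad1, Gad2, Rpsa-ps10, B3glct and Fry in each wild type library (circles) and each library labelled knockout (triangles), with the group mean and SD beside the points (n = 3). The groups overlap for the first 3 genes, and Rpsa-ps10 has a mean of 0.7966 CPM in wild type against 33.57 CPM in the libraries labelled knockout.

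A single gene passed the threshold between the groups. Rpsa-ps10, a processed copy of the ribosomal protein gene Rpsa on chromosome 3 (150072658 to 150073542), rose from 0.7966 ± 0.1271 to 33.57 ± 3.561 CPM (SD, n = 3 each), a log2 fold change of 5.41 ± 0.23 (SE; edgeR adjusted p = 0.000455). The copy is 99.32% identical to its parent transcript over its 885 bases, so reads could be split between them and the value is uncertain as a level of the copy. By edgeR no gene passed as lower in the libraries labelled knockout. At an unadjusted p under 0.05 there were 1249 of 17221 genes, 772 higher and 477 lower, and DESeq2 called 15 genes higher and 6 lower. Groups were fully separated for 2241 genes, or 13%, where chance gives 10%. Leaving out wild type replicate 1 raised the calls to 306 higher and 15 lower, leaving out wild type replicate 4 gave 3 higher, and leaving out knockout replicate 7 gave 5 higher and 1 lower, among them 4 Y-linked genes and Xist. Without wild type replicate 1, the wild type group held only replicates 3 and 4, the libraries with the most reads outside annotated genes. Calls in that setting cannot be told apart from this difference between libraries. With protein-coding genes alone there were 0 calls in either direction by edgeR, at 1048 genes with an unadjusted p under 0.05. That setting leaves out Rpsa-ps10, which is a pseudogene, so it does not test this call.

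The higher genes with the smallest p-values that did not pass were another processed copy, a glycosyltransferase and copies of mitochondrial genes. Hmgb1-ps7, a copy of the chromatin protein gene Hmgb1 with 98.61% identity, had 7, 1 and 0 counts in the wild type libraries and 414, 250 and 362 in the libraries labelled knockout (edgeR adjusted p = 0.0715). B3glct, which encodes a glucosyltransferase of the endoplasmic reticulum, had 17.02 ± 2.464 CPM in wild type and 55.05 ± 6.408 CPM in the libraries labelled knockout (SD, n = 3 each; edgeR adjusted p = 0.0715). Gm28437 and Gm28661, unprocessed pseudogenes on chromosome 1 near 24613189, had log2 fold changes of 2.38 ± 0.30 and 1.97 ± 0.29 (SE; edgeR adjusted p = 0.267 and 0.511). Both are 100% identical to mitochondrial transcripts, mt-Co3 and mt-Co2, and cannot be separated from them by sequence. Gm42614 had 1, 0 and 0 counts in the wild type libraries and 24, 14 and 20 in the libraries labelled knockout (edgeR adjusted p = 0.511). It lies on chromosome 5 (51482752 to 51484305), inside the span of Ppargc1a on the same strand (51454250 to 51567726).

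The lower genes with the smallest p-values were led by Fry, the homolog of the Drosophila gene furry. It had 301.9 ± 100.8 CPM in wild type and 59.4 ± 9.496 CPM in the libraries labelled knockout (SD, n = 3 each), a log2 fold change of -2.34 ± 0.28 (SE; edgeR adjusted p = 0.24). Vipr1, a receptor for vasoactive intestinal peptide, had a log2 fold change of -1.34, Rsph10b, a radial spoke gene of motile cilia, -2.02, Stag3, a cohesin subunit of meiosis, -1.15, and Epha2, an ephrin receptor gene, -0.59, each with an edgeR adjusted p of 0.637. Hmgb1-ps7, B3glct, Gm28437, Gm28661, Fry, Vipr1, Rsph10b, Stag3 and Epha2 all passed with DESeq2. Without wild type replicate 1, Hmgb1-ps7 and Fry passed at an edgeR adjusted p of 0.0153, B3glct, Gm28437 and Gm28661 at 0.0243, Vipr1 at 0.0464 and Rsph10b at 0.0494. Hmgb1-ps7 also passed without wild type replicate 4 (edgeR adjusted p = 0.0161) and with 1 surrogate variable (0.00927). Hmgb1-ps7, B3glct, Gm28437 and Fry passed without the filter on low counts (edgeR adjusted p = 0.000128, 0.00114, 0.00413 and 0.00718). With the GC and length offset Hmgb1-ps7, Gm28437 and Fry passed (edgeR adjusted p = 6.1e-06, 0.0118 and 0.000399). These gains did not hold throughout. Without wild type replicate 3, knockout replicate 5 or knockout replicate 6, Hmgb1-ps7 had an edgeR adjusted p of 0.258, 0.578 and 0.736. In each of these 3 settings, and with limma-voom, Rpsa-ps10 was the only gene called.

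Near Gtf2ird1, 0 of the 282 tested genes within 10 Mb passed the edgeR threshold, against 1 of 16938 elsewhere (Fisher's exact test, two-sided p = 1). The 1 called gene, Rpsa-ps10, lies on chromosome 3, so this comparison could not show an excess near Gtf2ird1. At an unadjusted p under 0.05 there were 21 of 282 genes near it and 1228 of 16938 elsewhere (Fisher's exact test, two-sided p = 0.908). DESeq2 called 2 genes in this window. Without wild type replicate 1, edgeR called 4. The 4 genes with an unadjusted p under 0.001 within 20 Mb, Stag3, Rsph10b, B3glct and Fry, all lay between Gtf2ird1 and the end of the chromosome. The Williams region list, with 21 tested members beside Gtf2ird1, had a median log2 fold change of -0.14 and a mean of 0.00. None of its members passed, adjusted over all genes or adjusted over the list alone. Eln, the elastin gene, had the smallest p, with 4.567 ± 0.4658 CPM in wild type and 8.927 ± 2.101 CPM in the libraries labelled knockout (SD, n = 3 each; edgeR adjusted p = 0.637). Camera gave this list an adjusted p of 0.228.

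**Figure D3:**
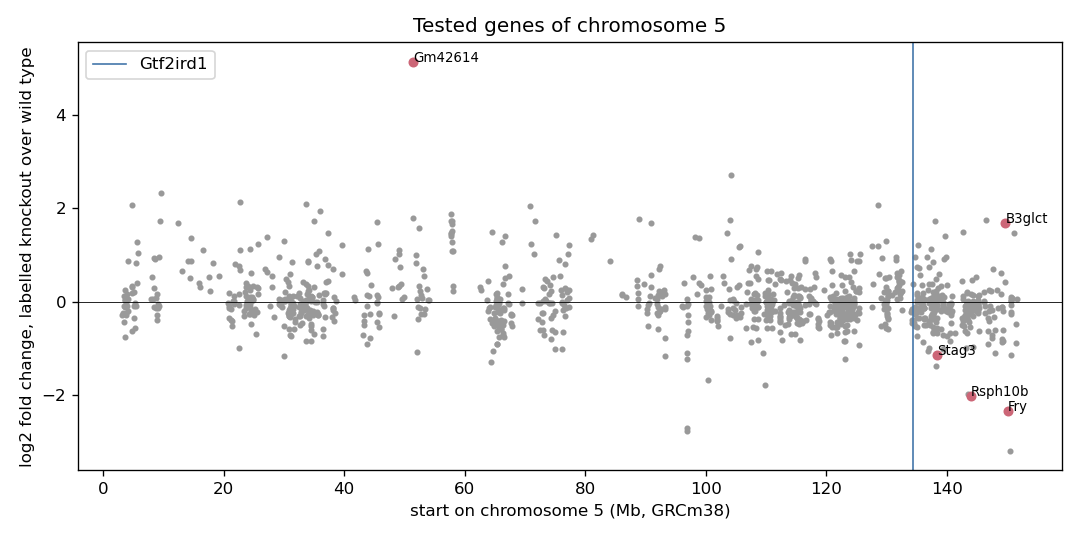
Log2 fold change of the libraries labelled knockout over wild type for each tested gene of chromosome 5 against its start (Mb, GRCm38), with Gtf2ird1 as a vertical line and genes with an unadjusted p under 0.001 in colour and named. B3glct (1.69) and Fry (-2.34) lie near the end of the chromosome.

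Glial and vascular lists were placed higher in the libraries labelled knockout by camera at its preset correlation alone, and no member passed by itself. All 16 astrocyte markers had positive log2 fold changes, with a median of 1.77 (1.30 to 3.16 without 1 library), and camera placed the list above other genes at an adjusted p of 2.12e-09, against adjusted p = 0.432 with an estimated correlation. Slc7a10, an amino acid transporter of astrocytes, had 9.428 ± 7.521 and 42.76 ± 23.13 CPM (SD, n = 3 each), and Fgfr3 had 39.72 ± 38.89 and 170.1 ± 96.56 CPM (SD, n = 3 each). Of 18 oligodendrocyte and myelin genes, 17 were positive, with a median of 1.36 (0.93 to 2.91 without 1 library) and a camera adjusted p of 2.03e-07 (adjusted p = 0.432 with an estimated correlation). Gjc3 and Aspa had log2 fold changes of 1.74 and 1.34. All 12 oligodendrocyte precursor markers were positive (median 1.29, or 0.84 to 2.33 without 1 library, camera adjusted p = 3.44e-05, adjusted p = 0.432 with an estimated correlation), among them Olig1 and Olig2 at 1.22 and 1.21. Of 20 endothelial and mural cell markers 18 were positive (median 1.02, or 0.60 to 1.59 without 1 library, camera adjusted p = 1.52e-05, adjusted p = 0.432 with an estimated correlation), led by Slco1c1, a thyroid hormone transporter of brain vessels, at 2.26. Slco1c1 had 28.15, 10.87 and 4.28 CPM in wild type and 112.7, 39.72 and 57.76 CPM in knockout replicates 5, 6 and 7. The astrocyte marker Slc7a10 ranked the libraries in the same order, at 17.54, 8.065, 2.682, 67.12, 21.09 and 40.08 CPM. Whether the vascular list moved apart from the astrocyte list was not tested. The microglia and macrophage list had a median of -0.24 and did not pass (camera adjusted p = 0.0648, adjusted p = 0.724 with an estimated correlation).

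The wild type libraries differed among themselves in the same lists. The astrocyte median was 57.6 CPM in wild type replicate 1, 12.7 CPM in replicate 3 and 6.82 CPM in replicate 4, against 143, 57.3 and 81.1 CPM in knockout replicates 5, 6 and 7. The oligodendrocyte and myelin median was 24.7, 2.49 and 3.38 CPM in wild type and 27.1, 19.7 and 32.0 CPM in the libraries labelled knockout. Without wild type replicate 1, 11 of 16 astrocyte markers and 6 of 18 oligodendrocyte and myelin genes passed as higher by edgeR, and Fgfr3, Gjc3, Olig1 and Slco1c1 had an edgeR adjusted p of 0.046, 0.0263, 0.0385 and 0.0499. The microglia list, when wild type replicate 4 was left out, passed as lower, with a median of -0.44 (camera adjusted p = 1.82e-05, adjusted p = 0.581 with an estimated correlation), and without knockout replicate 6 with a median of -0.27 (camera adjusted p = 0.0279, adjusted p = 0.737 with an estimated correlation).

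Neuronal lists were also placed higher by camera at its preset correlation alone, with smaller medians. The pan-GABAergic list had a median log2 fold change of 0.53 over 23 tested members (0.22 to 1.29 without 1 library; camera adjusted p = 0.000694, adjusted p = 0.499 with an estimated correlation), with Maf at -0.36. The list no longer passed without wild type replicate 1 or replicate 3, at a camera adjusted p of 0.078 and 0.0694, or with the Y-linked covariate, at 0.0959. Medians were 0.84 for VIP, LAMP5 and SNCG interneuron markers (13 tested, camera adjusted p = 0.000359), 0.52 for somatostatin interneuron markers (7 tested, 0.0147), 0.40 for striatal projection neuron markers (9 tested, 0.00959) and 0.36 for glutamatergic markers (19 tested, 0.00813). Without 1 library these medians ran from 0.56 to 1.68, from 0.23 to 0.81, from 0.22 to 0.87 and from 0.16 to 0.61. All 4 lists had adjusted p = 0.432 with an estimated correlation, and with 1 surrogate variable the VIP, somatostatin and glutamatergic lists did not pass (camera adjusted p = 0.0875, 0.0875 and 0.0501). The parvalbumin list did not pass, with a median of 0.17 (9 tested, camera adjusted p = 0.228, adjusted p = 0.432 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial genes, had 2.414 ± 2.4 and 8.64 ± 3.692 CPM (SD, n = 3 each), and passed when wild type replicate 1 was left out (edgeR adjusted p = 0.0394). The somatostatin list lost its call without wild type replicate 3 or 4, at a camera adjusted p of 0.19 and 0.0514.

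Receptor, channel and synapse lists were placed higher in the same way, by camera at its preset correlation alone. GABA receptor and synapse genes had a median of 0.68 (22 tested, 21 positive, camera adjusted p = 1.02e-06, adjusted p = 0.432 with an estimated correlation), with Gabrg1 at 2.06 and Gabbr2 at 1.57. Without 1 library the list median ran from 0.43 to 1.48, Gabrg1 from 1.57 to 4.04 and Gabbr2 from 1.17 to 2.72, and both genes passed when wild type replicate 1 was left out (edgeR adjusted p = 0.0262 and 0.0282). Glutamate receptor genes had a median of 0.64 (24 tested, 22 positive, camera adjusted p = 1.02e-06, adjusted p = 0.432 with an estimated correlation), with Grin2c at 2.08. Grin2c had 38.24, 13.05 and 6.449 CPM in wild type and 127.4, 37.75 and 81.37 CPM in knockout replicates 5, 6 and 7. The astrocyte marker Ntsr2 was close to it, at 36.85, 16.4, 6.392, 120.2, 38.64 and 70.47 CPM. Whether the receptor lists moved apart from the astrocyte list was not tested. Potassium channel genes had a median of 0.53 (30 tested, 28 positive, 1.19e-05), synaptic vesicle and release genes 0.43 (37 tested, 30 positive, 0.000123), and sodium and calcium channel genes 0.40 (25 tested, 20 positive, 0.00842), the values in brackets being camera adjusted p, with adjusted p = 0.432 with an estimated correlation for all 3. Axon guidance genes had a median of 0.49 (50 tested, 42 positive, camera adjusted p = 1.58e-05, adjusted p = 0.432 with an estimated correlation) and neuropeptide genes 0.67 (10 tested, 7 positive, camera adjusted p = 0.0298, adjusted p = 0.507 with an estimated correlation). Without 1 library the medians ran from 0.38 to 1.05 for glutamate receptor, 0.27 to 1.29 for potassium channel, 0.21 to 0.57 for synaptic vesicle, 0.11 to 0.66 for sodium and calcium channel, 0.26 to 0.90 for axon guidance and 0.25 to 1.22 for neuropeptide genes. The sodium and calcium channel list did not pass without wild type replicate 3 (camera adjusted p = 0.207), nor the neuropeptide list without wild type replicate 3 or 4 (0.0677 and 0.341). With library totals alone both lists had a camera adjusted p of 0.0557.

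Among lists of cell state, immediate early genes had a median of 0.61 (23 tested, 21 positive, camera adjusted p = 3.64e-05, adjusted p = 0.499 with an estimated correlation), with Egr1 at 0.81 and Egr3 at 1.40, the latter passing without wild type replicate 1 (edgeR adjusted p = 0.0243). The median ran from 0.13 to 1.28 without 1 library, and the list did not pass without wild type replicate 4 (camera adjusted p = 0.547), nor with 1 surrogate variable (0.259). Circadian clock genes had a median of 0.44, or 0.33 to 0.68 without 1 library (19 tested, 16 positive, camera adjusted p = 0.000231, adjusted p = 0.432 with an estimated correlation), with Npas2 at 2.07 and Bhlhe41 at -0.58. Heat shock and stress genes and nuclear oxidative phosphorylation genes passed with small medians of 0.21 and 0.12 (camera adjusted p = 0.044 and 0.00842, adjusted p = 0.724 and adjusted p = 0.759 with an estimated correlation), and their medians turned negative without wild type replicate 4, at -0.01 and -0.03 (camera adjusted p = 0.294 and 0.604). The stress list also lost its call without knockout replicate 6 (camera adjusted p = 0.661), and the oxidative phosphorylation list without wild type replicate 3 or knockout replicate 5 (0.0722 and 0.158). Cytosolic ribosomal protein genes (78 tested, median 0.03), interferon and antigen presentation genes (22 tested, -0.17), Polycomb and histone modifier genes (46 tested, 0.00) and blood cell genes (5 tested, 0.00) did not pass, at camera adjusted p = 0.243, 0.214, 0.768 and 0.75. The ribosomal list passed upward without wild type replicate 1 or knockout replicate 7 (camera adjusted p = 3.63e-08 and 0.0444, adjusted p = 0.519 and adjusted p = 0.778 with an estimated correlation). The blood list did so without wild type replicate 3 (camera adjusted p = 0.0184, adjusted p = 0.564 with an estimated correlation), and the interferon list passed downward without wild type replicate 4 (camera adjusted p = 1.63e-05, adjusted p = 0.581 with an estimated correlation). With the GC and length offset the stress and oxidative phosphorylation medians were also negative, at -0.06145 and -0.08988. Camera still placed both lists upward there, without a call (camera adjusted p = 0.0937 and 0.0897).

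In all, camera placed 20 of the 27 tested lists higher and 0 lower, and with an estimated correlation or with fry 0 lists passed, the smallest adjusted p being 0.432 and 0.311. No member of any list passed, adjusted over all genes or adjusted over the list alone, and 0 lists were enriched for called genes by Fisher's exact test. The 1 called gene, Rpsa-ps10, stood on no list, so that test could not have shown enrichment. The serotonin receptor list and the list of ependymal and choroid plexus markers had low medians, of at most 0.242 and 0.475 CPM in any library. Htr3a was the highest serotonin receptor gene, between 2.83 and 14.1 CPM.

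Sex-linked transcripts divided the libraries in part along the groups. Xist had 1560, 2180 and 3820 CPM in wild type replicates 1, 3 and 4 and 2370 CPM in knockout replicate 7, with 0 and 3 reads in knockout replicates 5 and 6. Ddx3y, on the Y chromosome, had 167 and 197 CPM in knockout replicates 5 and 6, 1 read in knockout replicate 7 and 0 reads in the wild type libraries.

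The share of reads on the processed copies, among reads on parent and copy together, was far larger in the libraries labelled knockout than in wild type. For Rpsa-ps10 the share was 0.214%, 0.395% and 0.473% in wild type replicates 1, 3 and 4 and 14.3%, 15.2% and 14.3% in knockout replicates 5, 6 and 7. For Hmgb1-ps7 it was 0.186%, 0.0899% and 0% in wild type, the count of 0 allowing up to 0.227%, and 13.1%, 12.7% and 11.5% in the libraries labelled knockout. A further copy of Hmgb1, Hmgb1-ps3, had 1, 0 and 0 reads in wild type and 15, 14 and 17 in the libraries labelled knockout. The parents Rpsa and Hmgb1 had log2 fold changes of -0.26 ± 0.21 and -0.13 ± 0.17 (SE; edgeR adjusted p = 0.705 and 0.824).

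**Figure D4:**
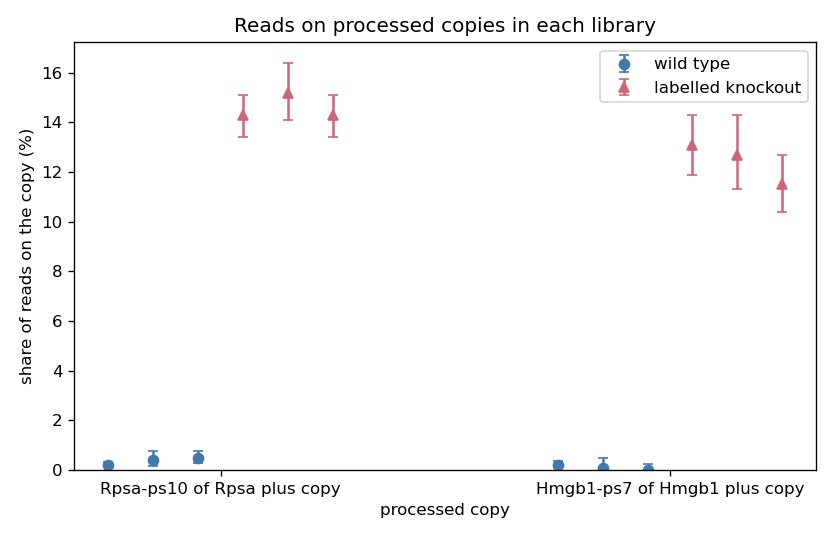
Share of reads on the processed copy among reads on parent and copy (%), per library, for Rpsa-ps10 and Hmgb1-ps7, with exact 95% binomial intervals that cover counting error only. Libraries labelled knockout (triangles) lie between 11.5% and 15.2% and wild type libraries (circles) at most at 0.473%.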

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

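No paired analysis was possible because the groups share no replicate number. The covariate for Y-linked reads and the looser threshold near Gtf2ird1 were chosen after the data were seen. The log2 fold change of Rpsa-ps10 stayed between 5.22 and 5.54 in the settings that tested it, with an adjusted p of at most 0.0155, and that of Gtf2ird1 was positive and did not pass in any setting (0.04 to 0.82). Genes higher in the libraries labelled knockout numbered 15 with DESeq2, 4 without a filter on low counts, 2 with 1 surrogate variable, 3 with the GC and length offset and 3 at an adjusted p of 0.1. With protein-coding genes only they numbered 0, since that setting leaves out the pseudogene Rpsa-ps10. Lower genes numbered 6 with DESeq2, and 1 each without a filter, with the GC and length offset and with the Y-linked covariate. Leaving out 1 library in turn gave 1 to 306 higher and 0 to 15 lower genes, 0 to 4 called genes near Gtf2ird1 and 0 to 7 lists enriched for called genes, the highest values without wild type replicate 1. Near Gtf2ird1, 2 genes were called with DESeq2 and 2 at an unadjusted p of 0.001. Lists with a set-wide shift numbered 0 with an estimated correlation, also without any 1 library (chosen after the data were seen), and 0 with fry. Apart from the removal of Rpsa-ps10 with protein-coding genes only, the cause of these differences was not tested.

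Some signs turned, and the cause was not tested. With library totals alone, which moved the median of all genes from -0.03 to 0.11, and with limma-voom, Hba-a1 was 0.02958 and 0.04144. With 1 surrogate variable, Alas2 was -0.01416 and Hbb-bt -0.25, and the medians of the heat shock, oxidative phosphorylation and ribosomal lists were -0.03997, -0.06482 and -0.19. The first 2 of these lists then lost their call, and the ribosomal list passed as lower. With the GC and length offset, Alas2 was -0.02537, Dnaja1 -0.07192, Atp5g3 -0.0012 and Cbx6 -0.02598. The medians of the heat shock and oxidative phosphorylation lists turned to -0.06145 and -0.08988. Both lists lost their call (camera adjusted p = 0.0937 and 0.0897), though camera, which compares a list with other genes, still placed them upward. With the Y-linked covariate, Gad1 was -0.26, Chodl -0.21, Alas2 -0.38, Hbb-bt -0.20, Bmi1 -0.0048, Jarid2 -0.09282 and the oxidative phosphorylation list -0.03267. None of the genes named here passed in the main analysis or in these settings.

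Leaving out 1 library in turn, log2 fold changes ranged from -0.03943 to 1.265 for Gad1, from -0.7986 to 0.0148 for Osbpl3, from -0.6183 to 0.09533 for Hba-a2, from -0.5595 to 0.2913 for Hba-a1, from -0.1063 to 0.6728 for Alas2, from -0.2374 to 0.4551 for Hbb-bt and from -0.04403 to 1.856 for Jarid2. Medians ranged from -0.01129 to 0.4263 for the heat shock list and from -0.028 to 0.3128 for the oxidative phosphorylation list. Medians of lists that kept their sign moved too, and among lists that passed the relative range was widest for immediate early (0.13 to 1.28), sodium and calcium channel (0.11 to 0.66), pan-GABAergic (0.22 to 1.29), neuropeptide (0.25 to 1.22) and potassium channel genes (0.27 to 1.29). The cause was not tested.

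Other list calls at the preset correlation changed without a change of sign, and the cause was not tested. With 1 surrogate variable the VIP, somatostatin, glutamatergic, immediate early and neuropeptide lists did not pass (camera adjusted p = 0.0875, 0.0875, 0.0501, 0.259 and 0.579), and the microglia and interferon lists passed as lower (6.79e-06 and 0.000291). With the Y-linked covariate the pan-GABAergic, heat shock and neuropeptide lists did not pass (camera adjusted p = 0.0959, 0.268 and 0.149). With library totals alone the sodium and calcium channel and neuropeptide lists did not pass (camera adjusted p = 0.0557 for both) and the microglia list passed as lower (0.0476). Without a filter the heat shock and neuropeptide lists did not pass (camera adjusted p = 0.0682 and 0.0769). With protein-coding genes only the heat shock list did not pass (camera adjusted p = 0.067) and the microglia list passed as lower (0.0276).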

Other observations

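All tests weighed in this part were chosen after the results they bear on had been seen, except the 10 Mb window around Gtf2ird1 and the gene lists, which were fixed before the data were examined.

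Genes of immature neurons were well above genes of mature neurons in every library. Over 15 genes of immature neurons and neuroblasts, a list written after the data were seen, the median was 95.8 ± 79.0 CPM in wild type and 148 ± 55.9 CPM in the libraries labelled knockout (SD, n = 3 each). Over 12 genes of mature neurons, also listed afterwards, it was 6.65 ± 3.13 and 9.0 ± 0.761 CPM (SD, n = 3 each). Dcx, a microtubule protein of migrating neuroblasts, ranged from 72.2 to 510 CPM and Sox11 from 95.8 to 525 CPM, against 11.2 to 34.0 CPM for Snap25 and 1.25 to 5.84 CPM for Rbfox3. Sp8 and Dlx1, transcription factor genes of the GABAergic lineage, ranged from 26.6 to 113 and from 43.7 to 203 CPM. Proliferation genes were detected in each library, with Mki67 between 12.3 and 105 CPM and Top2a between 10.2 and 99.6 CPM. Wild type replicates 1 and 3 had the lowest values of Dcx, Sox11, Mki67 and Top2a, and wild type replicate 4 had the highest values of Dcx and Sox11.

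Microglial genes were abundant in libraries described as Gad2+ neurons. The median microglial marker was at least 19.9 times the median GABAergic marker in every library, none of the 19 microglial genes stood on another list (0 shared), and the most abundant, Csf1r, was at 7370 CPM or more. Microglial RNA as a small admixture to neuronal RNA was argued against, since the highest neuronal list median in any library, that of immature neuron genes, reached 19.2% of the microglial median, with at most 5.03% for GABAergic and 0.889% for mature neuron genes. The GABAergic percentage restates the ratio of microglial to GABAergic medians given above and adds no separate evidence. How the cells were isolated is not given in the sources used here. The source of the microglial transcripts, whether other cells were collected and whether samples were exchanged with another collection stayed untested, and no biological explanation was tested.

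The libraries labelled knockout had a larger share of reads on 2 processed copies, and 4 genes of chromosome 5 within 20 Mb of Gtf2ird1 had an unadjusted p under 0.001. Gm42614, also on chromosome 5 and with an unadjusted p under 0.001, lies outside that window, at 51482752. A candidate explanation is a sequence difference from the reference that moves reads of Rpsa and Hmgb1 to near-identical copies. Among the libraries labelled knockout, the highest copy share was 1.06 times the lowest for Rpsa-ps10 and 1.14 times for Hmgb1-ps7. Of 10000 random gene pairs, 3.18% and 13.8% were as steady, so only Rpsa-ps10 was steadier than 95% of pairs. Parent plus copy changed by -0.039 and 0.0673 (log2). Neither value decides between moved reads and expression of the copies. A copy expressed in proportion to its parent would also hold a steady share, and the copies make up only a small part of the sum. The explanation therefore cannot be told apart from expression of the copies, for either copy. The 95% intervals of the Hmgb1-ps7 shares overlapped in knockout replicates 5, 6 and 7 (11.9% to 14.3%, 11.3% to 14.3% and 10.4% to 12.7%). Its ratio of 1.14 is therefore no evidence against a constant share. Another candidate explanation is DNA of another strain left around the targeted gene. Of 12 combinations of window and threshold, the fixed 10 Mb window at an unadjusted p under 0.001 held 2 of 282 genes against 15 of 16938 (Fisher's exact test, p = 0.0309, adjusted p = 0.14). The 20 Mb window held 4 of 522 (Fisher's exact test, p = 0.00145, adjusted p = 0.0174). At an unadjusted p under 0.01 the 10 Mb and 20 Mb windows held 4 of 282 and 10 of 522 genes (Fisher's exact test, p = 0.35 and 0.0351, adjusted p = 0.7 and 0.14). There was no excess at an unadjusted p under 0.05 (Fisher's exact test, p = 0.908 and 0.797). The explanation therefore cannot be told apart from chance at the fixed window, although all 4 DESeq2 calls on chromosome 5 lay within 20 Mb. Rpsa lies on chromosome 9 and Gtf2ird1 on chromosome 5, so DNA left around the targeted gene would not include Rpsa itself. Where the reads on Rpsa-ps10 arose was not tested, so the position of Rpsa does not decide the question for this copy. Hmgb1, the parent of Hmgb1-ps7, starts at 149046702 on chromosome 5, near B3glct and Fry, which start at 149678230 and 150118645. It lies outside the 10 Mb window around Gtf2ird1 but inside the 20 Mb window, so DNA left around the targeted gene could include Hmgb1. Where the reads on Hmgb1-ps7 arose was not tested either. An effect of the loss of Gtf2ird1 on these genes stays open as untested.

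The placing of glial, vascular and neuronal lists as higher by camera may reflect the makeup of the libraries. A lower share of the main cell type, raising all other types alike, would keep the gap between astrocyte and GABAergic lists equal. Within wild type the gap was 1.734, -0.1909 and -3.066 (log2) in replicates 1, 3 and 4. This argues against such a share as the only source of the spread among the wild type libraries. Between the groups, the gap was larger by 1.54 ± 1.41 (SE, log2) in the libraries labelled knockout, with an exact permutation p of 0.4 (two-sided, smallest possible 0.1). For the group difference, a lower share of the main cell type therefore cannot be told apart from a change in single types at 3 against 3. The sex of the animals cannot be told apart from the group either: 16 lists stayed higher with Y-linked reads as a covariate, but that comparison rests on knockout replicate 7 as the only library labelled knockout without such reads. An effect of the genotype on glial or neuronal genes stays open as untested.

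Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 1 gene and the highest other split 2, and 3 splits gave at least as many as the real one. For the lists the real split gave 20 and the highest other 18, and 1 split, the real one, gave as many. The splits are too few for a share under 0.05.

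The region of chromosome 9 around Rpsa, chosen after its genes had been seen, held 7 of 145 genes with an unadjusted p under 0.01 within 10 Mb, against 158 of 17076 elsewhere (Fisher's exact test, two-sided p = 0.000498), and 1 of 145 against 16 at an unadjusted p under 0.001 (p = 0.134). Rpsa starts at 120127689 on chromosome 9. DESeq2 called Vipr1 and Lyzl4 lower, and they start at 121642716 and 121577843 on that chromosome. It called Ky higher, which starts there at 102505750. Gm10925 and Gm29216, which lie beside Gm28437 and Gm28661 on chromosome 1 and match mt-Atp6 and mt-Co1 over at least 98.2% of their length, had log2 fold changes of 2.53 and 2.21.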
